A study of Mus musculus with 19 samples.

How the data were processed

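RNA of whole aorta from male C57BL/6 mice had been sequenced in 19 libraries, which the labels place in 6 groups: wild type and Fbn1 hypomorph (the mgR allele, a mouse model of Marfan syndrome) at 16, 30 and 60 days of age. The labels gave 3 libraries per genotype at 16 days, 4 per genotype at 30 days, and 3 hypomorph and 2 wild-type libraries at 60 days. Per the labels' protocols, polyadenylated RNA was made into strand-marking libraries and read from both ends.

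Per the submitters' processing notes, the reads were handled with TopHat2 2.0.8, Bowtie2 2.1.0, SAMtools 0.1.7 and Cufflinks 1.3.0 on the mouse build mm9; settings were not given in the sources used here. Per the file headers, the authors' tables hold 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of a library) for each gene and group, pooled over the libraries of the group. No library has a value of its own, so no spread between animals could be computed, and which libraries entered each pool was not given in the sources used here. Total counts and sequencing depth are unknown, and low FPKM values did not fall on whole multiples that would give reads back. The table of 16 days also holds the authors' own test of each gene: a score (the test statistic), a p-value and a q-value (an adjusted p), as deposited, and a status that says whether a test was made. The tables of 30 and 60 days carried no test. Values of the 3 ages came from separate tables, so comparisons were made within a table, and levels set beside each other across ages were normalised separately. In the tables of 30 and 60 days, wild-type values were listed 3 times; these listings differed for 17 genes at 30 days and 11 at 60 days, in each case because a listing was 0, and the larger value was kept. A further 2 groups of rows, 1 per table, matched no labelled sample and were not used here.

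Each table listed 37668 genes by Ensembl identifier, of which 32638 matched a symbol. Some of the most abundant transcripts were listed at 0, such as Col1a1, Col1a2, Col3a1, Sparc and Eln at 16 and 30 days, which shows that 0 can mean a failed estimate. A gene listed at 0 in either group was therefore not compared. The difference between genotypes was log2(FPKM + 1) of the hypomorph minus that of wild type, which understates changes of low genes, for genes with a mean of at least 1 FPKM. Plain ratios of FPKM are given as folds. At 16 days a gene was called where the authors' q-value was below 0.05. Recomputed Benjamini-Hochberg values over the 12738 tested genes differed from the deposited q-values by at most 4.46e-06. The deposited log2 ratio at 16 days is wild type over hypomorph, and its sign was reversed here to give hypomorph over wild type. Standard errors at 16 days are those implied by the deposited log2 ratio and statistic. At 30 and 60 days no p-value was computed, since genes are not replicates.

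Before the data were examined, 35 gene lists were fixed, 1 of them a check of the sex label. A list's median difference is described by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. This describes the pooled values and is not a test between animals. Random lists draw genes singly, so their range takes no account of members that vary together. Intervals of list medians come from 2000 resamplings of the members. The plan had assumed values per library, with a test at each age, of the change with age, and of gene lists; the pooled values allowed none of these. The rule for naming genes had been Fbn1, the 12 largest and 12 most negative changes among called genes whose libraries did not overlap, up to 4 members of each list, and 8 genes per direction for each change with age. The overlap of libraries could not be applied, and at 30 and 60 days the rule became the size of the difference alone. Genes outside the rule are marked as chosen after their values were seen. Predicted gene models and pseudogenes were skipped, and some genes that the rule names are not reported here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots from matplotlib 3.10.9; transcript lengths and neighbours came from GENCODE M21.

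The calculations were tested on simulated data. For the comparison at 16 days, 12543 genes were simulated with the implied standard errors, and 10.4% of genes changed 1.5-fold, 22.4% of genes changed 2-fold and 72.7% of genes changed 4-fold were called, with 3 calls among 12343 unchanged genes. Each fold was given to 66 or 67 genes. Noise came from the same standard errors that the test divides by, so few false calls were fixed in advance. Whether those errors measure the spread between animals was not checked. Of 200 simulated unchanged lists of 20 genes, 6% fell outside the middle 95% of random lists. The simulated lists were themselves drawn at random with independent noise, so a small share outside was fixed in advance. It does not show how lists of genes that vary together behave. Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, scaling by the median ratio, other thresholds and, added after seeing the data, random lists matched on transcript length too.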

Results

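The data were pooled expression values of mouse aorta in FPKM, 1 per gene for wild type and 1 for the Fbn1 hypomorph at each of 3 ages. Mice with this allele make too little fibrillin-1, the main protein of the microfibrils that scaffold elastic fibres. The values pooled 3 libraries per genotype at 16 days, 4 at 30 days, and 3 hypomorph and 2 wild-type libraries at 60 days, going by the labels. Because the libraries were pooled before deposit, no value has an SD or n, and differences at 30 and 60 days have no replicate check. The listed values of a group summed to between 502130 FPKM in the hypomorph at 30 days and 602727 FPKM in wild type at 60 days.

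Fbn1 itself was lower in the hypomorph at every age. At 16 days it stood at 41.4 FPKM in the hypomorph against 146 in wild type, and in the authors' deposited table the log2 ratio was -1.82 (implied SE 0.47, q-value 0.00622). At 30 days the values were 40.9 and 133.9 FPKM, a 3.27-fold difference, and at 60 days 24.6 and 52.7 FPKM, a 2.14-fold difference. Fbn1 (ENSMUSG00000027204) was placed on chromosome 2 from 125126330 to 125333729 of mm9, a span shared with 1 predicted gene. Of the labels' sex, the Y-linked Ddx3y was present in every group, from 11.5 FPKM in wild type at 60 days to 25.5 FPKM in the hypomorph at 30 days. A pooled value cannot show whether every library in a group was male.

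**Figure D1:**
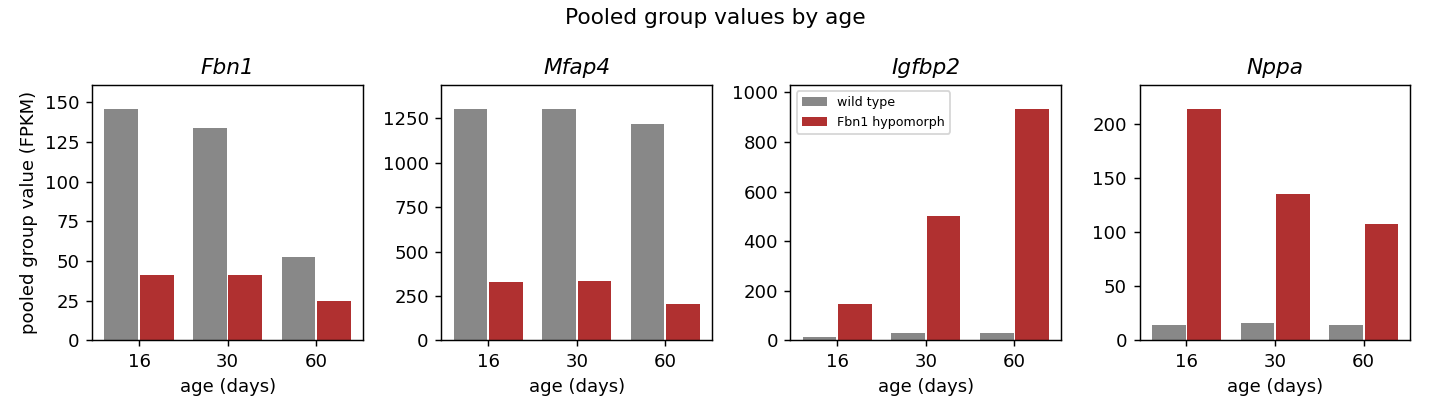
Bars give the pooled FPKM of 4 genes in wild type (grey) and hypomorph (red) at 16, 30 and 60 days; each panel has its own axis from 0, and there are no error bars because each group has 1 pooled value. Mfap4 stood near 1305 FPKM in wild type and 327 in the hypomorph at 16 days, while Igfbp2 reached 934 FPKM in the hypomorph at 60 days.

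The first comparison asked how hypomorphic aorta differed at 16 days. Transcripts of the microfibril and of T cells were among those lower in the hypomorph, and transcripts of macrophages, of the natriuretic peptide Nppa and of the matricellular protein Ccn3 were among those higher. In the authors' deposited table, 357 of 12738 tested genes were called, 170 higher and 187 lower in the hypomorph. A test had failed for 5235 further genes, including 302 of the 793 genes with a mean of 100 FPKM or more, so many abundant aortic transcripts had no test.

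Among elastic fibre genes, Mfap4, a microfibril-associated glycoprotein, was at 327 FPKM against 1305 in wild type, a 3.99-fold difference with a log2 ratio of -1.99 in the authors' deposited table (implied SE 0.28, q-value 2.87e-10). Its span is shared with Mapk7, so its reads are uncertain. Fbln1, encoding fibulin-1, was at 71.2 against 110.8 FPKM (q-value 0.000372), and Loxl1, which cross-links elastin, at 238 against 344 FPKM (q-value 0.0388), both in the authors' deposited table. Of 19 tested members 3 were called, all lower, 16 did not pass and 11 had no test; adjusted over the list alone, 3 were lower and 1 higher. Mfap5, chosen after its values were seen, had no test, with 391 FPKM in the hypomorph and 1179 in wild type.

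Of 23 tested macrophage genes 7 were called, all higher in the hypomorph, and 16 did not pass; adjusted over the list alone, 13 were higher and 1 lower. Itgam, an integrin chain of myeloid cells, was at 5.87 against 2.37 FPKM with a log2 ratio of 1.31 in the authors' deposited table (implied SE 0.20, q-value 4.14e-08). The chemokine Ccl9 was at 42.7 against 14.3 FPKM (q-value 0.0176 in the authors' deposited table). The macrophage list had a median log2 difference of 0.92 (95% interval over members 0.55 to 1.02), at percentile 100 of the random lists. Haemoglobin transcripts stood higher too: the erythroid list had a median of 1.15, with Hba-a2, whose reads overlap those of its copy Hba-a1, at 5944 against 2081 FPKM, and none of its 7 tested members was called; adjusted over the list alone, 6 were higher.

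T cell transcripts and a few neutrophil transcripts were lower in the hypomorph at 16 days. Trbc2, a constant segment of the T cell receptor, was at 1.20 against 22.7 FPKM (log2 ratio -4.24, implied SE 0.66, q-value 3.76e-08 in the authors' deposited table); its near-identical neighbour Trbc1 was at 0.551 against 14.9 FPKM, and reads shared by the pair make both values uncertain. Of 15 tested lymphocyte genes 5 were called, all lower, and 10 did not pass; adjusted over the list alone, 5 were lower. Genes of immature thymocytes stood lower too, with 9 of 12 at least 2-fold lower on plain ratios. The neutrophil calcium-binding proteins S100a8 and S100a9 were at 1.97 against 17.8 and 1.94 against 23.6 FPKM, with q-values of 0.000686 and 5.23e-08 in the authors' deposited table. With Ngp, chosen after its values were seen, they made up the 3 calls, all lower, among 12 tested genes of the neutrophil and mast cell list; 9 did not pass, and adjusted over the list alone 5 were lower. The list did not stand lower as a whole: 5 of 9 compared members were higher, with a median of 0.31 at percentile 99.8, which became -0.036 without the filter on level.

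Interferon-stimulated genes lay on the lower side at 16 days, with a list median of -0.28 at percentile 0 and 14 of 22 compared members lower, but the 95% interval over members, -0.48 to 0.03, included 0. Of 19 tested 1 was called, Iigp1, an interferon-induced GTPase, at 7.42 against 26.4 FPKM (q-value 5.54e-05 in the authors' deposited table), and 18 did not pass; adjusted over the list alone, 2 were lower. By size alone, 135 genes were at least 2-fold higher and 179 lower at this age.

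Single genes with large differences included Nppa, atrial natriuretic peptide, at 214 against 14.3 FPKM; its span is shared with 1 predicted gene, so its reads are uncertain. Ccn3 was at 651 against 165 FPKM (q-value 0.00016 in the authors' deposited table), and the cartilage proteoglycan Acan at 30.6 against 8.92 FPKM (q-value 7.42e-05 in the authors' deposited table). Lower in the hypomorph were Mylk2, a myosin light chain kinase of skeletal muscle, at 0.670 against 5.93 FPKM (q-value 3.76e-08), Chad at 6.95 against 23.0 FPKM (q-value 0.000902), and the growth factor Igf1 at 23.5 against 56.2 FPKM (q-value 1e-07), all in the authors' deposited table. Skeletal muscle markers moved beside Mylk2 at 16 days: of 9 compared, 8 were lower, with a median of -0.32 at percentile 0.23. Of 10 tested, Tnnt3 was called lower at 1.10 against 5.68 FPKM (q-value 3.29e-07) and Acta1, whose listed span overlaps many genes, higher at 12.8 against 3.29 FPKM (q-value 0.0026), both in the authors' deposited table. The other 8 did not pass, and adjusted over the list alone, 3 were lower and 1 higher. At 30 and 60 days the list did not stand lower (medians 0.08 and 0.43, percentiles 61.2 and 96.1). Mylk2 stayed lower at those ages (log2 differences -2.69 and -2.64). Igfbp2, which binds insulin-like growth factors, was at 147 against 12.6 FPKM, but its test had failed; it was chosen at this age after its values were seen.

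At 30 days the largest differences were in inflammatory transcripts, higher in the hypomorph. The acute phase gene Saa3 was at 48.2 FPKM against 0.498 in wild type, the cytokine Il6 at 18.1 against 0.0593, Il1b at 13.1 against 0.224, and the monocyte chemokine Ccl2 at 46.6 against 1.85. Of 30 compared inflammation genes 24 were at least 1.5-fold higher and 0 as much lower, with a list median of 2.07 at percentile 100. The macrophage list had a median of 1.61 and the interferon list 0.87, with Irf7 at 40.1 against 10.4 FPKM. Cell cycle genes had a median of 1.03, with 28 of 37 at least 1.5-fold higher; Top2a, a topoisomerase of dividing cells chosen after its values were seen, was at 15.1 against 5.79 FPKM.

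Genes listed for the synthetic smooth muscle state also stood higher at 30 days, though values of whole aorta do not show which cells made them. The list of that smooth muscle state had a median of 0.81, with Igfbp2 at 502 against 30.7 FPKM, Spp1 (osteopontin) at 80.9 against 7.44 and Col8a1 at 39.4 against 8.91. Of the TGF-beta list, 7 of 31 members were at least 1.5-fold higher and 1 lower (median 0.30). Mfap4 stood 3.91-fold lower at 334 against 1304 FPKM, but the medians of the elastic fibre list (-0.07, percentile 46.4) and the collagen list (0.02, percentile 82.5) lay within the range of random lists. Of 28 compared elastic fibre genes, 8 were at least 1.5-fold lower and 2 as much higher. Eln, Col1a1, Col1a2 and Col3a1 were listed at 0 and could not be compared. The contractile list had a median near 0 (-0.10, percentile 37.0), with 8 of 33 compared members at least 1.5-fold lower and 3 as much higher. At this age Acta2 was listed at 0 in both groups and Flna at 0 in the hypomorph, so neither could be compared. Lower in the hypomorph were C7, a complement component, at 11.2 against 90.9 FPKM, and Vipr2 at 1.21 against 11.2. Markers of other tissues moved with genotype: the adipocyte list had a median of -1.06, with Fasn at 57.0 against 198.9 FPKM, and the cardiomyocyte list 1.08, with Actc1, chosen after its values were seen, at 141 against 59.9 FPKM. In all, 523 genes were at least 2-fold higher and 185 lower among 13930 compared.

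At 60 days macrophage, inflammatory, interferon and antibody transcripts stood higher than in wild type. The macrophage list had a median of 2.47 (95% interval over members 2.11 to 2.67), with the protease Ctss at 199 against 18.2 FPKM and Adgre1 at 27.0 against 2.26. The inflammation list had a median of 1.67, with 23 of 31 members at least 1.5-fold higher and 2 lower. The interferon list had a median of 1.26, with Oas2 at 9.53 against 0.954 FPKM. Igkc, an antibody light chain, was at 344 against 9.83 FPKM and Jchain, which joins secreted antibodies, at 40.3 against 1.06; antibody gene segments share reads, so single values are uncertain. Of 24 lymphocyte genes, the 14 that reached the minimum level were all at least 1.5-fold higher (median 1.49, or 2.29 with a pseudocount of 0.1), but most were below that level in wild type and entered through the hypomorph's value. Without the filter all 24 were higher, 21 at least 1.5-fold, with a median of 1.07. Igfbp2 was at 934 against 27.6 FPKM and Saa3 at 66.0 against 0.328.

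Endothelial and adventitial fibroblast genes were lower at 60 days. Their lists also stood lower at 30 days, with medians of -0.31 (percentile 0.05) and -0.57 (percentile 0), respectively. At 16 days the endothelial median was -0.15 (percentile 0.44), while the fibroblast median of -0.10 (percentile 17.8) lay within the range of random lists. The endothelial list had a median of -0.77, with 14 of 21 members at least 1.5-fold lower; Pecam1 was at 78.1 against 266 FPKM and Nos3, endothelial nitric oxide synthase, at 7.84 against 29.8. The fibroblast list had a median of -1.09, with 13 of 18 at least 1.5-fold lower; Gsn was at 873 against 3738 FPKM and Pi16 at 262 against 929. Chad was at 4.44 against 75.3 FPKM, Angptl7 at 11.6 against 139.5 and C7 at 10.1 against 133.8. Of the markers of other tissues, the adipocyte list had a median of 0.37, opposite in sign to 30 days, with 24 of 28 members higher, and the cardiomyocyte list 0.41. In all, 774 genes were at least 2-fold higher and 276 lower among 13992 compared. The median of all compared genes was 0.11 above 0 at 60 days, so small list medians at this age are to be read relative to it; scaling by the median ratio removed 0.12 and left 670 higher and 345 lower.

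**Figure D2:**
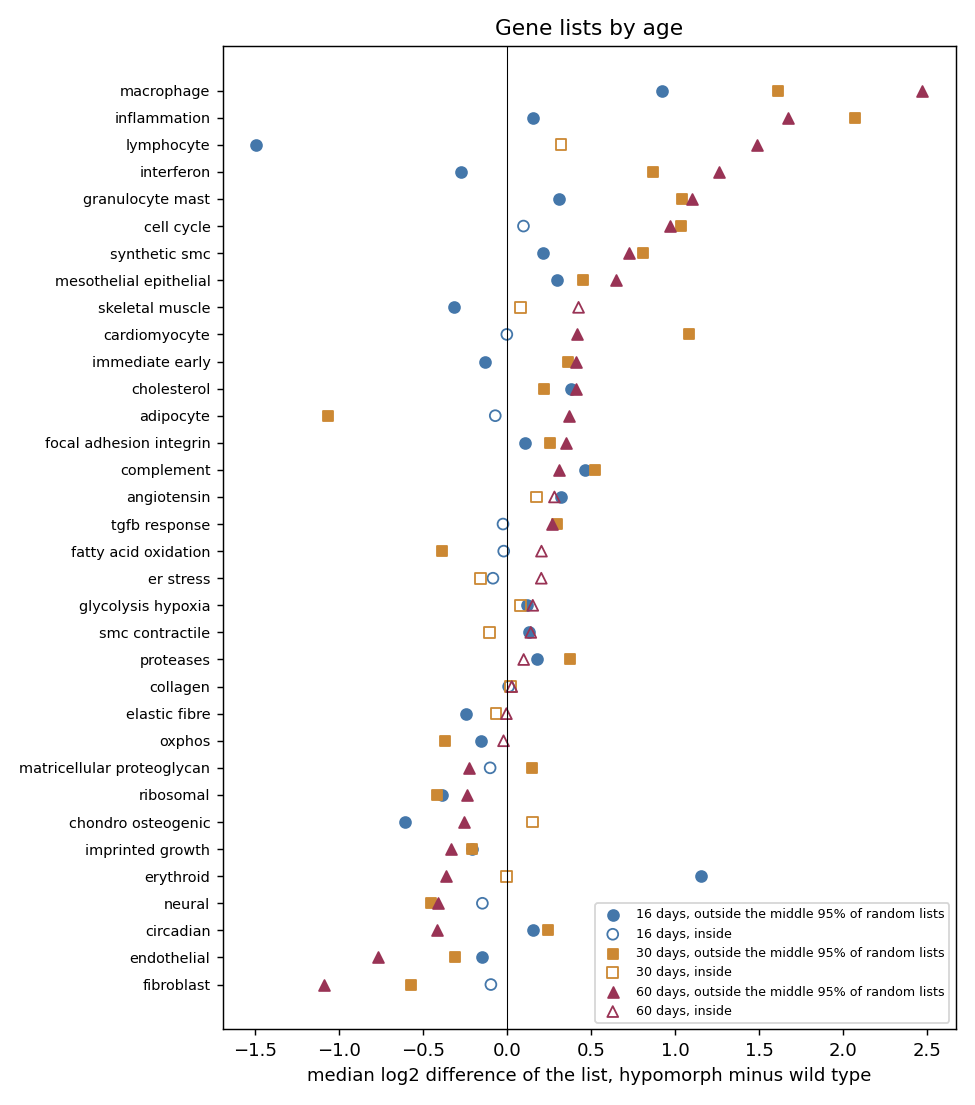
Each row is a gene list fixed beforehand and each symbol its median log2(FPKM + 1) difference, hypomorph minus wild type, at 16 days (circles), 30 days (squares) or 60 days (triangles); filled symbols lie outside the middle 95% of random lists matched on expression. The macrophage list had medians of 0.92, 1.61 and 2.47 at the 3 ages. Of 34 lists, 14 lay above and 10 below that range at 16 days, 16 and 8 at 30 days, and 15 and 9 at 60 days.

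Differences also went with transcript length across compared genes, longer transcripts standing higher in the hypomorph (Spearman rho 0.21, 0.31 and 0.18 at 16, 30 and 60 days; genes are not independent replicates). With random lists matched on length as well as level, a setting chosen after seeing the data, 22 of the 24 lists outside the range stayed outside at each age, and 2, 0 and 1 others came to lie outside it at 16, 30 and 60 days. Those that came inside were the respiratory chain and integrin adhesion lists at 16 days, the matricellular and proteoglycan list and the clock list at 30 days, and the erythroid and ribosomal protein lists at 60 days.

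Comparing ages asked whether the genotype difference changed with time, and no test of that change could be run. Of the 170 genes called higher at 16 days, 152 were compared at 30 days and 140 of these were again higher; of the 187 called lower, 148 were compared and 124 of these were again lower, leaving Fbn1 out. Uncalled tested genes kept their direction in 73.3% and 64.9% of cases, respectively, so part of this share is not particular to the calls. At 60 days 124 of 149 were again higher, against 76.0% of uncalled genes, and 103 of 140 again lower, against 52.0%; 6 of the former and 15 of the latter stood at least 1.5-fold the other way. The log2 difference, hypomorph minus wild type, was higher by 1 or more at 30 than at 16 days for 289 genes and lower for 99. The counts were 482 and 221 from 16 to 60 days, and 185 and 122 from 30 to 60 days. Differences at 30 and 60 days correlated across genes (Pearson r 0.76, Spearman rho 0.70, over 13613 genes, which are not independent replicates); for 16 and 30 days r was 0.56, and for 16 and 60 days 0.45. At 30 and 60 days alike, 386 genes were at least 2-fold higher, against 24.5 for independent lists. At all 3 ages 66 genes were at least 2-fold higher and 36 lower, the latter including Fbn1, Mfap4, Mylk2, Vipr2 and C7.

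Some genes stood on opposite sides of wild type at different ages. S100a9 was lower at 16 days and higher at 30 days (30.2 against 2.99 FPKM), and Cthrc1, a collagen triple helix repeat protein, was at 11.4 against 31.6 FPKM at 16 days and 68.7 against 19.4 at 30 days. Trbc2 was higher in the hypomorph at 60 days (6.59 against 1.69 FPKM). The interferon list had medians of -0.28, 0.87 and 1.26 at the 3 ages, the first with an interval that included 0. Levels at different ages come from separately normalised tables.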

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

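All settings here were chosen before the data were examined, except random lists matched on transcript length too. No paired analysis was possible because each group was deposited as 1 pooled value. For the same reason leaving out replicates, the fit over all libraries, limma, set tests, tests of the change with age and tests of age within wild type were not run, nor was any other split of the samples. Depth is unknown, so it sets no limit that can be given here. Fbn1 stayed lower at each age under every setting run, and the numbers of lists outside the middle 95% of random lists stayed within 1.5 times under every setting. Single list medians left their interval over members 7 times under median-ratio scaling, 5 times with a mean of 5 FPKM, 5 times with a pseudocount of 0.1 and 2 times without a filter. Among them, the cell cycle list at 60 days went from 0.97 to 0.49 with a mean of 5 FPKM and to 1.38 with a pseudocount of 0.1, and the ribosomal protein list at 60 days from -0.24 to -0.36 under scaling. Median-ratio scaling and dropping the filter kept every count of genes within 1.5 times.

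Requiring a mean of 5 FPKM and adjusting again left 206 calls at 16 days, 103 higher and 103 lower, in place of 357; fewer genes enter. With that minimum, genes at least 2-fold different at 16 days were 91 higher and 87 lower, 51.1% higher in place of 43.0%, and those at least 2-fold higher 273 at 30 days and 400 at 60 days. Shared 2-fold genes became 36 lower at 16 and 30 days, 26 lower at 16 and 60 days and 188 higher at 30 and 60 days. Genes whose signed difference was higher by 1 or more at the later age became 114 from 16 to 30 days, 188 from 16 to 60 days and 106 from 30 to 60 days, and those with a lower one 141 from 16 to 60 days and 68 from 30 to 60 days.

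A pseudocount of 0.1 gave 242 genes at least 2-fold higher and 279 lower at 16 days, 325 lower at 30 days and 437 lower at 60 days, since it lets low genes differ more. Shared genes became 139 higher and 99 lower at 16 and 30 days, 140 higher and 74 lower at 16 and 60 days, and 151 lower at 30 and 60 days. The signed difference was higher by 1 or more at the later age for 435 genes from 16 to 30 days and 312 from 30 to 60 days, and lower for 158 and 205. At a 1.5-fold threshold, 512 genes were higher and 519 lower at 16 days, 1214 and 721 at 30 days, and 1665 and 829 at 60 days.

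Without a filter the granulocyte and mast cell list at 16 days turned from a median of 0.31 to -0.036; the cause was not tested. For 88 values of named genes the pseudocount of 0.1 moved the difference by more than the gene's implied standard error at 16 days, or by more than the median one at the later ages. No named gene with a difference of at least 1.5-fold changed sign under any of these settings.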

Other observations

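The tests on neighbours of Fbn1, on scaling and on plain ratios of thymocyte and B cell genes were chosen after the results they measure had been seen in part. Transcripts encoded by the mitochondrial genome, also picked after their values were seen, stood lower in the hypomorph at the later ages. At 60 days all 13 compared were lower, with a median log2 difference of -1.07, and mt-Cytb was at 4088 against 8502 FPKM. At 30 days 9 of 9 were lower, with a median of -0.56, and at 16 days 11 of 12, with a median of -0.12. The list of nuclear-encoded respiratory chain genes had medians of -0.16, -0.37 and -0.02 at 16, 30 and 60 days, with 48, 51 and 30 of 54 members lower. Among random lists matched on transcript length too, these lay at percentiles 26.4, 1.36 and 86.1, and scaling by the median ratio gave -0.14 at 60 days.

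Arntl and Ciart, chosen among the clock genes after their values were seen, stood on opposite sides of wild type at 30 and 60 days. Arntl was at 1.57 FPKM in the hypomorph against 3.52 in wild type at 30 days and 2.85 against 1.04 at 60 days, while Ciart, a repressor of the clock, was at 9.30 against 2.93 FPKM at 30 days and 11.4 against 16.6 at 60 days. The clock list of 18 genes had medians of 0.16, 0.24 and -0.42 at 16, 30 and 60 days, with 7, 6 and 14 members lower. The hour at which tissue was taken is not given in the sources used here.

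Ribosomal protein mRNAs were lower in the hypomorph, with list medians of -0.39, -0.42 and -0.24 at 16, 30 and 60 days. Scaling between the pooled groups argues poorly for this, since the list lay -0.39, -0.45 and -0.35 from the median of all genes. These mRNAs are short. Among random lists matched on level and length the list was at percentile 0 at 16 days and 1.5 at 30 days. At 60 days it was at percentile 7.09, where a length trend could account for it. Length was that of the longest annotated transcript of each gene, in 5 bins within each level bin. The transcripts present in the tissue may differ in length from it. Shorter transcripts stood lower across all compared genes (Spearman rho 0.21, 0.31 and 0.18 between difference and length), as a difference in RNA quality or library preparation between the pools could give. Length measured in this way did not account for the list at 16 and 30 days. A trend with the length of the transcripts present was not excluded at those ages, and a length trend stays open at 60 days. No value here separates RNA quality or library preparation as such from a difference between the genotypes, and these stay open.

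For the T cell transcripts lower in the hypomorph at 16 days, a candidate source is thymic tissue carried along in the wild-type libraries, since the thymus lies near the aorta. The log2(FPKM + 1) median of the 12 immature thymocyte genes (-0.41, or -0.06 for the 3 at a mean of 1 FPKM, the version run first) decides nothing, since 6 of them could not reach the bound of -1 on that scale. On plain ratios all 12 were lower, 9 at least 2-fold, with a median log2 ratio of -2.16 (95% interval over members -3.30 to -0.75), as thymic tissue would give; Rag1 was at 0.138 against 1.62 FPKM. In the authors' deposited table Themis (q-value 0.000411) and Ccr9 (q-value 7.77e-06) were called lower, 2 of the 5 tested, as was Dntt, outside the list and chosen after its values were seen, at 0.192 against 2.58 FPKM (q-value 6.96e-09). For lymph node or blood the median ratio of 7 B cell genes was 0.18, but only 1 of them reached a mean of 1 FPKM, so that source cannot be told apart from a difference between the genotypes, which was not tested.

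Several genes called at 16 days lie near Fbn1 on chromosome 2, among them Tyro3, Ehd4, Duoxa1, Gatm and Fbln7, which were chosen after their values were seen. A flanking segment of another strain, kept with the targeted allele, could give such a cluster. The 100 tested genes around Fbn1 held 6 calls, more than 90.2% of 9668 other windows of that size. Those windows slid along by single genes and overlap, so they are not independent. They had a median of 3 calls and a highest count of 9, and 948 of them held 6 or more. All 6 had the same direction at 30 days and 5 at 60 days, but most calls elsewhere kept theirs too, so a segment cannot be told apart from calls that fall there by chance. None of the 6 lay within 1 Mb of Fbn1 (0% of the calls), which argues against an effect limited to that distance as their source. Only 9 genes were tested there, too few to say whether the allele changed its neighbours at all.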
